A study of Sphingomonas melonis TY with 9 samples.

How the data were processed

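Total RNA depleted of ribosomal RNA was sequenced as paired-end Illumina reads from 9 libraries of Sphingomonas melonis TY, a nicotine-degrading alphaproteobacterium. The libraries form 3 groups of 3, taken from the sample titles and genotypes. WT is the unmodified strain, dsnc251 is the snc251 deletion with an empty vector, and dsnc251_comp is the same deletion with a plasmid that overexpresses SNC251. The labels give WT no vector. All cultures were grown in LB at 30 °C and 200 rpm and collected at an OD600 of 0.6, per the labels' protocols. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

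The deposited values are FPKM, fragments scaled by feature length and library size, in 1 table of 4351 features by 9 libraries. Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq are named in the software list, per the submitters' processing notes. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Of the features, 4017 are annotated genes and 334 are predicted (29 named as sRNA and 305 others). Of the predicted ones, 330 overlap an annotated gene on the other strand. Without a stated strand setting the split of reads within such a pair is uncertain. All features lie on 1 sequence with a placeholder name. Coordinates are printed as deposited.

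The depth was recovered from the FPKM steps. In each library the FPKM multiplied by the feature length was a whole multiple of 1 value. Of 30796 non-zero values worth 1000 reads or fewer, 100% came out within 0.01 of a whole number. The recovered totals lay between 2861521 and 3239215 reads per library. A single read in a 1 kb feature was worth 0.316 to 0.372 FPKM. The scale between the deposited libraries followed median-ratio factors and not the totals. WT replicate 2 had a deposited factor of 1.08, a median-ratio factor of 1.07 and a total of 0.986, each relative to the arithmetic mean of the libraries. A count of 0 in a library allows up to 3 reads at the 95% level, for counting error only.

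Before the data were examined, the comparisons, the named-gene rule, the gene lists and most alternatives were fixed. The main test planned for raw counts was a count model, with limma on log2(FPKM + 1) as the stated fallback for FPKM. The table held FPKM, so the fallback was used. Features with a mean FPKM of 1 or more over the 9 libraries were tested (4095, with 256 left out). A single limma fit (version 3.58.1, R 4.3.3) with a mean-variance trend covered the 3 groups. It had 6 residual degrees of freedom, a prior of 3.37 degrees of freedom and no replicate block. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

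Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 24 lists, 23 had at least 5 tested members. The list of antibiotic resistance and vector markers had 4 and was left out. Members were picked by fixed patterns on symbol or product. Matching with regard to case was chosen after the names and exploratory per-gene values had been seen. The patterns took in 38 members of 8 lists by part of an unrelated name. These stayed in the lists, and the lists without them are an added alternative. Without them, translation factors and tRNA synthetases went from 51 to 35 members and chaperones and proteases from 31 to 24.

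Named genes met 3 conditions: an adjusted p under 0.05, a mean of at least 10 FPKM in either group, and no overlap between the groups' values. The 6 highest and 6 lowest log2 fold changes with a known product were taken in each comparison. Added to them were the called member with the smallest p in each direction of every list that passed camera, hfq, any feature named snc251, and 6 genes called in opposite directions. The lowest genes against WT all lay in 2 coordinate blocks with almost no reads outside WT. The 6 lowest outside the blocks were therefore added after their values were seen. Further examples from the lists were also chosen after their values were seen.

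A block was a run of neighbouring features with at most 2 reads each over the 6 libraries of the deletion background. It had to hold at least 10 features with 6 or more WT reads and ended at the outermost of these. This definition was set after the loss was seen. The correlation of log2 fold changes and the overlap of calls between comparisons that share libraries were set beside 100 simulations of unchanged groups. The fit was tested on simulated data with 50 genes of at least 10 FPKM changed at each of 4 sizes. In dsnc251 against WT it recovered 52% of genes changed 1.5-fold, 80% at 2-fold, 92% at 3-fold and 98% at 4-fold, with 8 false calls among 3895 unchanged features. In dsnc251_comp against dsnc251 the shares were 54%, 78%, 92% and 98%, with 7 false calls of 3894. In dsnc251_comp against WT they were 52%, 92%, 92% and 96%, with 12 of 3892. Reads were simulated for each feature on its own, so false calls from genes that vary together are not covered.

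The alternatives covered the scaling, limma-voom on the recovered reads, low-value filters, pseudocounts of 0.1 and 10, and the 6 libraries of the compared groups. They also covered a replicate block, stricter thresholds and each library left out in turn. The alternatives without the 2 blocks, without predicted features, with other list members and with a length trend removed were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.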

Results

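RNA abundance was measured in 9 rRNA-depleted libraries of S. melonis TY grown in LB to an OD600 of 0.6. The series asks how snc251, a small regulatory RNA, takes part in the response to hyperosmotic stress. The labels describe growth in LB and name no osmotic treatment, so the comparisons are between strains. There were 3 libraries each of the wild type (WT), the snc251 deletion with an empty vector (dsnc251, called the deletion strain) and the deletion with an SNC251 plasmid (dsnc251_comp, called the complemented strain). Recovered totals were 3122965, 3085744 and 2861521 reads in WT replicates 1 to 3. They were 3186137, 3239215 and 3179155 in the deletion strain and 3192104, 3151323 and 3161532 in the complemented strain.

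No feature of the table carries the name snc251, so the targeted RNA was not analysed here and the labels have no check by its reads. The gene for Hfq, an RNA chaperone that many small RNAs use, stood at 1449 ± 113 FPKM (SD, n = 3) in WT. It was at 1450 ± 134 in the deletion strain and 1475 ± 187 in the complemented strain, with limma adjusted p = 1.00, 1.00 and 0.925 in the 3 comparisons. Spearman correlations across features were 0.981 to 0.991 within groups and 0.943 to 0.982 between them. The first principal component held 73.7% of the variance and separated WT from the other groups. Without 2 coordinate blocks that had almost no reads outside WT, it held 30.9% and set the complemented strain apart, with the WT libraries at −21.9, −5.99 and −9.76 and the deletion strain at −2.27 to −0.348. The chi-square per degree of freedom between replicates was 3.95 to 20.7, and the highest values, 18.5 and 20.7, belonged to the pairs with WT replicate 1. No pair was as close as sampling noise, so each library counted once. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

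The deletion strain differed from WT first by 2 long stretches of the listed coordinates that had reads in WT and almost none in the deletion background. Block 1 ran from 2919783 to 3014064 (94282 bp, 89 features) and block 2 from 3181941 to 3382754 (200814 bp, 222 features), with 167876 bp between them. The 3 WT libraries held 28092 reads in block 1 and 16045 in block 2. The 6 libraries of the deletion and complemented strains together held 6 and 3. The blocks held 174 features with at least 30 WT reads, all with at most 2 reads in those 6 libraries, as the block definition requires. Outside the blocks, 0 of 3771 features with as many WT reads were this low. The map of reads along the coordinates shows both stretches and the expressed segment between them.

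**Figure D1:**
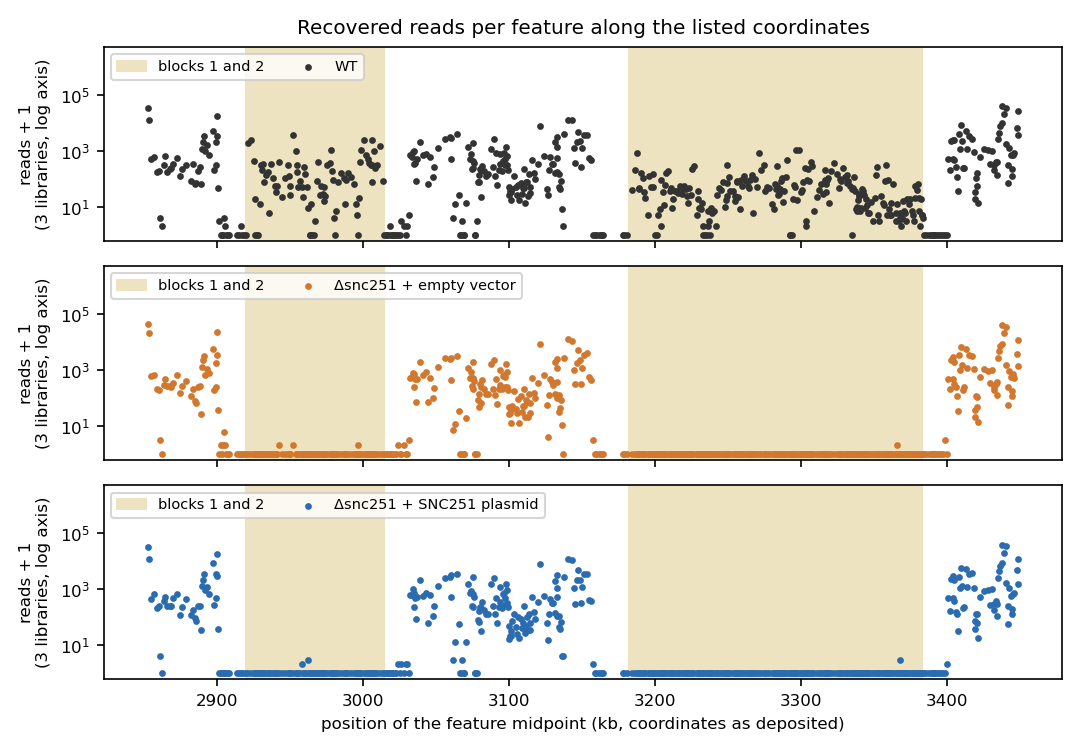
Recovered reads per feature, summed over the 3 libraries of each group (log axis, reads + 1), against the midpoint of the feature in kb as deposited. Shading marks blocks 1 and 2, where WT held 28092 and 16045 reads and the other 6 libraries together 6 and 3; unshaded stretches at the baseline in all 3 panels had almost no reads in any group.

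Block 1 held genes of surface polysaccharide synthesis. The tyrosine autokinase gene BJP26_RS13930, a regulator of polysaccharide chain assembly, was at 118 ± 7.34 FPKM (SD, n = 3) in WT and listed at 0 in all 6 other libraries. The same held for BJP26_RS13950, UDP-N-acetyl-D-mannosamine dehydrogenase, at 205 ± 19.0 in WT, and for the oxidoreductase gene BJP26_RS13585 at 125 ± 8.04. Toxin-antitoxin genes of both blocks, BJP26_RS13710 at 249.5 ± 41.9 and BJP26_RS15570 at 126.5 ± 18.4, and the partition gene BJP26_RS19690 (ParA) at 138 ± 31.2 in WT were also listed at 0. Block 2 held the genes of nicotine degradation, among them ndpC (6-hydroxypseudooxynicotine oxidase) at 15.7 ± 1.69, ndpB at 11.3 ± 2.50 and nicotine dehydrogenase BJP26_RS14845 at 7.25 ± 3.12 in WT, all listed at 0 elsewhere. The catalase gene BJP26_RS15265, at 54.0 ± 10.9 in WT, lay there too. Of the 149 members of the list of mobile elements, phage and toxin-antitoxin genes, 48 lay in the blocks (Fisher's exact test, adjusted p = 4.06e-19 over 24 lists). Of the 48, 32 had reads in WT. Envelope polysaccharide had 8 of 44 and amino acid biosynthesis 0 of 74 (Fisher's exact test, adjusted p = 0.0912 for both). This test takes genes as independent draws, which neighbours in 2 stretches are not, so its p-values are likely too small.

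Outside the blocks, the deletion strain had more catalase/peroxidase HPI transcript (BJP26_RS18015), a peroxide-degrading enzyme, at 2282 ± 181 FPKM against 1190 ± 272 in WT (log2 fold change 0.96, SE 0.18, limma adjusted p = 0.00541). Methionine synthase BJP26_RS13350 rose from 1354 ± 192 to 2283 ± 356 (0.75, SE 0.14, adjusted p = 0.00489). BJP26_RS07805, a fatty acid oxidation enzyme, rose from 232 ± 32.7 to 419 ± 92.5 (0.84, SE 0.17, adjusted p = 0.00651). The other 3 of the highest 6 with a known product were rhamnogalacturonan lyase BJP26_RS16575 (0.96), the PAP2 phosphatase gene BJP26_RS07070 (0.93) and the FecR family gene BJP26_RS20955 (1.19, from 5.32 to 13.2 FPKM). The calls of these last genes ended when single libraries were left out: adjusted p reached 0.0655 without WT replicate 3 for BJP26_RS16575, 0.0691 without the same library for BJP26_RS07070, and 0.137 without dsnc251 replicate 3 for BJP26_RS20955. Leaving out WT replicate 1, dsnc251 replicate 1 or dsnc251 replicate 2 ended some of them as well, with adjusted p from 0.0502 to 0.0959. Library-size scaling ended that of BJP26_RS20955 (0.0555).

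Of 239 tested features of 200 bp or less that lie outside the blocks, 49 were lower in the deletion strain and 2 higher. Outside the blocks, the gene with a known product other than tRNA that fell furthest among those named was BJP26_RS20835, a (2Fe-2S)-binding protein, from 413 ± 22.7 to 108 ± 14.6 FPKM (log2 fold change −1.94, SE 0.15, limma adjusted p = 5.84e-06). The tRNA genes BJP26_RS18785 (tRNA-Leu, −2.59) and BJP26_RS10940 (tRNA-Ser, −1.94) fell, at adjusted p = 0.00157 and 0.00217. They rest on few reads, 43 over the 3 WT libraries against 6 for tRNA-Leu and 124 against 32 for tRNA-Ser. Reads were also few for the next tRNA genes, 62 against 12 (tRNA-Trp), 23 against 5 (tRNA-Pro) and 39 against 11 (tRNA-Met). The calls of tRNA-Trp BJP26_RS11805 (−2.23), tRNA-Pro BJP26_RS11585 (−1.82) and tRNA-Met BJP26_RS17155 (−1.76) ended when single libraries were left out, with adjusted p up to 0.130, 0.114 and 0.108. Those highest values came without dsnc251 replicate 2, dsnc251 replicate 3 and WT replicate 3. The 3 calls also ended with a smooth trend on length removed from each library (adjusted p = 0.112, 0.0751 and 0.101), with log2 fold changes of −1.82, −1.41 and −1.36 left. In all, 19 of 44 tested tRNA genes were called lower (8 with the length trend removed) and 0 higher, and tRNA took 0.0751% to 0.0801% of WT reads against 0.0375% to 0.0458% in the deletion strain. The features called lower outside the blocks had a median length of 478.5 bp, against 762 bp for all tested features and 1096.5 bp for those called higher. With the length trend removed, the lower calls among those of 200 bp or less outside the blocks went from 49 to 27.

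Ribosomal protein genes split, with 13 of 54 higher and 9 lower in the deletion strain (20 and 12 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.161, 0.941 with an estimated correlation). A run of 9 neighbouring genes from BJP26_RS11725 (rpsQ) to BJP26_RS11765 (rplD) rose with a median log2 fold change of 0.56, rpsS (S19) from 4784 ± 398 to 7440 ± 321 FPKM (0.64, SE 0.10, limma adjusted p = 0.00178). Other members fell, rpmG (L33) from 755 ± 20 to 228 ± 24.5 (−1.73, SE 0.09, adjusted p = 2.62e-07) and ykgO (a second L36) from 799 ± 97.0 to 287 ± 32.2 (−1.47, SE 0.12, adjusted p = 7.81e-06). The alkyl hydroperoxide reductase gene ahpC, another peroxide scavenger, fell from 5162 ± 908 to 2316 ± 206 (−1.14, SE 0.15, adjusted p = 0.000354). In its list, oxidative stress defence, 3 of 39 members were higher and 4 lower, 2 of these in block 2 (camera adjusted p = 0.161; median 0.19, mean −0.12).

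Central carbon metabolism rose in the deletion strain, with 8 of 44 members higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 2.32e-05). Its adjusted p = 0.779 with an estimated correlation. The 2-oxoglutarate dehydrogenase genes of the citric acid cycle were among them, odhB from 1351 ± 56.9 to 2029 ± 199.9 FPKM (0.58, SE 0.08, limma adjusted p = 0.000976) and BJP26_RS07900 from 1023 ± 11.5 to 1369 ± 99.0 (0.42). The pentose phosphate gene rpiB fell from 186 ± 28.0 to 118 ± 12.1 (−0.65, SE 0.12, adjusted p = 0.00450). One of the 8, leuA, belongs to leucine synthesis and entered by part of its product name.

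Fatty acid oxidation and aromatic or nicotine catabolism had 13 of 64 members higher, 15 adjusted over the list alone, and 6 lower, all 6 in block 2 (camera adjusted p = 0.00840, higher). Its adjusted p = 0.239 with an estimated correlation, and the mean log2 fold change of −0.06 opposed the median of 0.21. Acyl-CoA dehydrogenase BJP26_RS01370 rose from 486 ± 25 to 693 ± 53.3 FPKM (0.51, SE 0.08, limma adjusted p = 0.00116). Translation factors and tRNA synthetases passed camera with 8 of 51 members higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0366; adjusted p = 0.779 with an estimated correlation). infB (IF-2) rose from 791 ± 14.5 to 1100.1 ± 80.1 and infA (IF-1) fell from 978 ± 155 to 638 ± 40.7. This call ended without WT replicate 2, WT replicate 3, dsnc251 replicate 2 or dsnc251 replicate 3 (adjusted p = 0.116, 0.0794, 0.0858 and 0.0545), and also with library-size scaling (0.26), without the 2 blocks (0.110) and with a length trend removed (0.136). Its member rpsS is a ribosomal protein, and 35 of the 51 members remain without those taken in by part of an unrelated name.

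Envelope polysaccharide genes fell as a list in the deletion strain, with 11 of 40 lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 9.89e-05; adjusted p = 0.0642 with an estimated correlation). Of the 11, 8 lay in the blocks, and without the blocks the list had adjusted p = 0.0538. Outside them, polysaccharide export gene BJP26_RS17220 fell from 256 ± 26.9 to 160 ± 11.9 FPKM (−0.68) and glycosyltransferase BJP26_RS07180 from 164 ± 14.0 to 103 ± 6.52 (−0.66). Of the 18 osmoprotection genes, 4 were higher and 0 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.161). They were the potassium pump genes kdpA, kdpB and kdpC (0.51, 0.42 and 0.46) and betA, choline dehydrogenase of glycine betaine synthesis, from 93.0 ± 4.34 to 140.1 ± 12.8 (0.58, SE 0.09, limma adjusted p = 0.00202).

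TonB-dependent receptors, outer membrane proteins for iron chelates and other large substrates, had 2 of 76 members higher and 15 lower, 6 of these in the blocks (camera adjusted p = 0.679; median 0.04, mean −0.25). The other lists had camera adjusted p from 0.0984 (chaperones and proteases, 0 higher and 1 lower of 31) to 0.902 (general stress response regulators, 0 and 0 of 14). They included mobile elements at 0.1 with 0 higher and 23 lower of 101, all 23 in the blocks (median 0.02, mean −0.77). fry, which tests whether a list's genes move on balance one way without comparing them with other genes, gave an adjusted p under 0.05 for 6 lists, all lower and all with members in the blocks.

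Over all 4095 tested features, limma called 682 in the deletion strain against WT, 202 higher and 480 lower. Of these, 208 lay in the blocks, all lower, and 474 outside them, 202 higher and 272 lower. The higher count of 202 became 309, 132 and 128 without WT replicates 1, 2 and 3, and 119 and 83 without dsnc251 replicates 2 and 3. Scaling by library size alone gave 71 higher and 785 lower calls (8.29% higher, against 29.6%) and shifted the median log2 fold change of all features to −0.16. The deletion strain carried a vector that the labels do not give to WT, and it shares the block loss with the complemented strain. Deletion, vector and loss therefore cannot be told apart here.

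The complemented strain against the deletion strain is the comparison closest to the small RNA itself, because both strains carry a vector and have almost no reads in the blocks. The phage shock genes, an envelope stress system, rose together. pspB went from 614 ± 68.5 to 1984 ± 287 FPKM (SD, n = 3; log2 fold change 1.69, SE 0.15, limma adjusted p = 0.000341), pspC from 625 ± 86.4 to 1969 ± 130.2 (1.66, SE 0.12, adjusted p = 3.76e-05) and pspA from 635 ± 35.6 to 1813 ± 261 (1.5, SE 0.16, adjusted p = 0.000902). They belong to a run of 10 neighbouring genes on 1 strand between 3766670 and 3769965 that all rose, with a median log2 fold change of 1.69. Genes of TonB-dependent receptors rose by similar amounts, BJP26_RS06795 from 70.3 ± 6.93 to 216 ± 22.3 (1.6, SE 0.11, adjusted p = 3.11e-05) and BJP26_RS16655 from 32.6 ± 4.97 to 98.5 ± 18.6 (1.56, SE 0.17, adjusted p = 0.000958). The aspartyl protease gene BJP26_RS10865 rose from 39.1 ± 4.37 to 105 ± 5.98 (1.41, SE 0.19, adjusted p = 0.00372). A hypothetical protein gene, BJP26_RS12935, rose further than these, from 109.7 ± 26.3 to 978 ± 61.0 (3.17, SE 0.20, adjusted p = 2.38e-05), and was at 111 ± 23.9 in WT. It was chosen after its values were seen.

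The gene that fell most among those named was BJP26_RS08005, glutathione-dependent formaldehyde dehydrogenase, from 361 ± 82.6 to 74.3 ± 1.85 FPKM (−2.24, SE 0.29, limma adjusted p = 0.00302). Its neighbour BJP26_RS08000 fell from 211 ± 51.9 to 53.9 ± 4.25 (−1.92, SE 0.31, adjusted p = 0.00781). Response regulator BJP26_RS09165 fell from 396 ± 29.0 to 102 ± 18.6 (−1.96, SE 0.14, adjusted p = 3.76e-05). Sensor histidine kinase BJP26_RS21155 fell from 194 ± 16.0 to 57.8 ± 5.90 (−1.73, SE 0.11, adjusted p = 3.11e-05). The xanthine dehydrogenase family genes BJP26_RS12830 and BJP26_RS12835 fell by 1.85 and 1.72 on the log2 scale (SE 0.23 each), at adjusted p = 0.00245 and 0.00372. WT itself was uneven for some of these genes, with 272 ± 133 FPKM for BJP26_RS08005 and 197 ± 102 for BJP26_RS08000. Over the 191 genes called lower, WT replicate 1 lay a median of 0.48 above the other WT libraries on the log2 scale, against 0.01 to 0.10 in 95% of random sets of like mean FPKM.

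**Figure D2:**
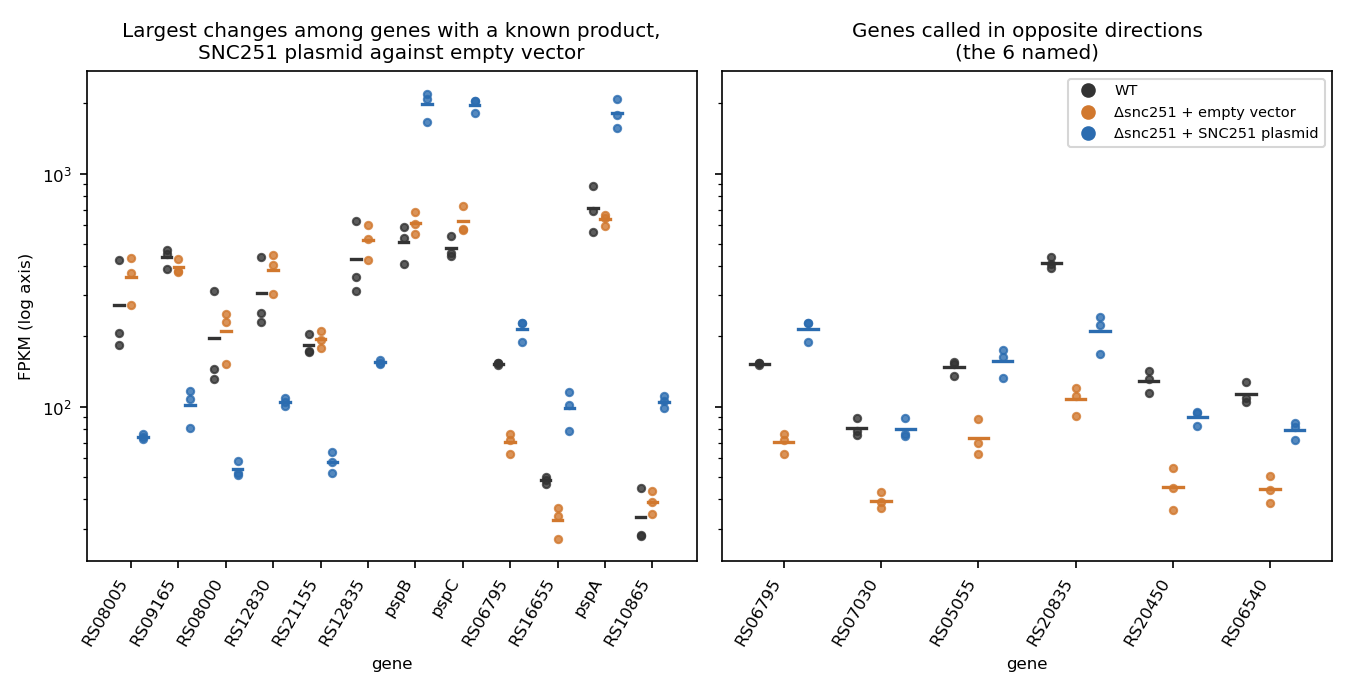
FPKM (log axis) of single libraries as points, with the mean of the 3 libraries of each group as a bar. The left panel has the 12 genes named for the complemented strain against the deletion strain, and the right panel the 6 genes named as called in opposite directions. pspB averaged 1984 FPKM with the SNC251 plasmid and 614 with the empty vector.

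TonB-dependent receptors rose in the complemented strain, with 8 of 76 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.00724; adjusted p = 0.928 with an estimated correlation). Besides those above, BJP26_RS04735 rose from 229.5 ± 25.5 to 471 ± 57.7 FPKM (1.03) and BJP26_RS07030 from 39.6 ± 3.12 to 80.2 ± 8.19 (1.00). The 1 lower member, BJP26_RS10800, went from 27.3 ± 5.03 to 15.0 ± 0.729 (−0.81). Its call ended without any 1 of dsnc251 replicates 2 and 3 (adjusted p = 0.0897 and 0.0974) or dsnc251_comp replicates 1, 2 and 3 (0.0747, 0.0812 and 0.0714). The list itself had adjusted p = 0.0831 without dsnc251_comp replicate 3.

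Chaperones and proteases passed camera in the higher direction with 1 of 31 members called, 5 higher adjusted over the list alone (adjusted p = 0.00262; adjusted p = 0.928 with an estimated correlation). Of the 31 members, 24 remain without those taken in by part of an unrelated name. The called member was clpB, a disaggregase, at 366 ± 51.1 and 503 ± 30.8 FPKM (0.47, SE 0.11, limma adjusted p = 0.0426). Its call ended without 7 of the 9 libraries: WT replicates 2 and 3 (adjusted p = 0.0683 and 0.0643), dsnc251 replicates 1 and 2 (0.125 and 0.0915) and dsnc251_comp replicates 1, 2 and 3 (0.0601, 0.147 and 0.130). It also ended with only the 6 libraries of the 2 groups (0.0797).

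Of the osmoprotection genes, 0 were higher and 5 of 18 lower in the complemented strain, the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.253, lower; median 0.02, mean −0.18). betA fell from 140.1 ± 12.8 to 99.3 ± 1.81 FPKM (−0.49, SE 0.09, limma adjusted p = 0.0163) and betB, the next enzyme of betaine synthesis, from 174 ± 13.6 to 127 ± 4.43 (−0.45). A mechanosensitive channel gene, BJP26_RS05210, fell from 233 ± 16.4 to 116 ± 5.50 (−1.0, SE 0.15, adjusted p = 0.00532). treZ, an enzyme of trehalose synthesis, fell from 71.9 ± 8.59 to 37.2 ± 6.32 (−0.94) and the OsmC family gene BJP26_RS17795 from 900 ± 159 to 381 ± 31.2 (−1.22). Catalase genes BJP26_RS19040 and BJP26_RS16910 fell by 1.62 and 1.33 on that scale, at adjusted p = 0.00499 and 0.00790, and the list of oxidative stress defence had 0 higher and 2 lower of 39 (camera adjusted p = 0.138).

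The remaining lists had camera adjusted p from 0.138 (ribosomal proteins, 0 of 54 called) to 0.974, and fry gave none an adjusted p under 0.05 (lowest 0.127, osmoprotection). Limma called 269 features in all, 78 higher and 191 lower, and with library-size scaling 101 higher and 203 lower. The count fell to 155 without dsnc251 replicate 1, 103 without dsnc251 replicate 3, 130 without dsnc251_comp replicate 2 and 139 without dsnc251_comp replicate 3. Without dsnc251_comp replicate 1 the lower calls went from 191 to 125. The cause was not tested.

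The complemented strain against WT shows how far the plasmid-bearing strain lay from the starting strain. pspC, pspB and pspA were at 480 ± 53.1, 510 ± 91.7 and 712 ± 161 FPKM in WT (SD, n = 3), which makes log2 fold changes of 2.04, 1.96 and 1.36 (SE 0.12, 0.15 and 0.16; limma adjusted p = 5.05e-07, 7.23e-06 and 0.000171). BJP26_RS10865 was also higher (1.65, SE 0.19, adjusted p = 0.000130). The PadR family gene BJP26_RS18470 went from 7.22 ± 5.26 to 20.3 ± 3.52 (1.65) and the helix-turn-helix gene BJP26_RS00450 from 26.3 ± 12 to 65.8 ± 8.33 (1.39), at adjusted p = 0.0478 and 0.0274. The call of the first ended without any library except WT replicate 2 (adjusted p from 0.0565 to 0.120), and without WT replicate 1 its log2 fold change was 0.96. It also ended with median-ratio factors (0.0501), library-size scaling (0.0708) and only the 6 libraries of the 2 groups (0.0845). That of the second ended without WT replicate 1 or 2 or any dsnc251_comp library (0.0612 to 0.0770).

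Outside the blocks, response regulator BJP26_RS09165 was at 437 ± 41.3 FPKM in WT and fell by 2.10 on the log2 scale (SE 0.14, limma adjusted p = 1.59e-06). rimO, a ribosomal protein S12 methylthiotransferase, fell from 128 ± 6.68 to 39.9 ± 1.09 (−1.66, SE 0.09, adjusted p = 3.50e-07). The histidine kinase BJP26_RS21155 fell by 1.65, BJP26_RS08005 by 1.75 and BJP26_RS08000 by 1.74, and tRNA-Met BJP26_RS17155 by 2.18 on the same scale. That tRNA gene had 39 reads over the 3 WT libraries and 9 over the 3 of the complemented strain. In this comparison 16 of 44 tRNA genes were lower (9 with the length trend removed) and 0 higher, and tRNA took 0.0437% to 0.0503% of reads. The 6 lowest named genes lay in the blocks and were those listed at 0 above: BJP26_RS13710, BJP26_RS13950, BJP26_RS19690, BJP26_RS15570, BJP26_RS13585 and BJP26_RS13930.

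Chaperones and proteases were higher as a list, with 12 of 31 higher and 1 lower, 14 and 2 adjusted over the list alone (camera adjusted p = 0.000262; adjusted p = 0.728 with an estimated correlation). The 31 again include members taken in by part of an unrelated name, and 24 remain without them. clpB went from 284 ± 25.3 to 503 ± 30.8 FPKM (0.83, SE 0.11, limma adjusted p = 0.000603), hslU, a protease ATPase, from 579 ± 55.8 to 1069 ± 120 (0.88) and the chaperone gene dnaK from 4534 ± 656 to 8112 ± 871 (0.84). The lower one, the HdeA/HdeB family chaperone BJP26_RS05980 (−0.61, adjusted p = 0.0407), kept its call without WT replicate 3 and without dsnc251 replicate 3 and lost it without each of the other libraries (0.0537 to 0.118), with the length trend removed (0.0559) and with only the 6 libraries of the 2 groups (0.0722).

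Envelope polysaccharide genes were lower, with 14 of 40 lower and 0 higher, 15 and 0 adjusted over the list alone (camera adjusted p = 6.06e-05; adjusted p = 0.0490 with an estimated correlation). Of the 14, 8 lay in the blocks. Ribosomal proteins passed in the higher direction with 16 of 54 higher and 7 lower, 21 and 9 adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.728 with an estimated correlation). rpmC (L29) rose from 3372 ± 139 to 5320.2 ± 606 FPKM (0.65, SE 0.10, limma adjusted p = 0.00125) while rpmG fell from 755 ± 20 to 281 ± 15.4 (−1.43, SE 0.09, adjusted p = 1.18e-06). This list lost its call without WT replicate 2, WT replicate 3 or dsnc251_comp replicate 1 (adjusted p = 0.0633, 0.276 and 0.383).

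Translation factors and tRNA synthetases had 9 of 51 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00170; adjusted p = 0.728 with an estimated correlation). As above, 35 of the 51 remain without members taken in by part of an unrelated name. fusA (elongation factor G) rose from 2800 ± 214 to 4374 ± 238 FPKM (0.65, SE 0.09, limma adjusted p = 0.000921) and aspS (aspartate-tRNA ligase) fell from 394 ± 31.6 to 244 ± 7.69 (−0.69, SE 0.08, adjusted p = 0.000108). Central carbon metabolism had 7 of 44 higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.000621; adjusted p = 0.728 with an estimated correlation). Its smallest p was that of leuA, the leucine synthesis gene, from 119 ± 5.18 to 206 ± 13.1 (0.78, SE 0.08, adjusted p = 9.00e-05), and rpiB fell from 186 ± 28.0 to 119 ± 0.846 (−0.63).

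The other lists had camera adjusted p from 0.0900 (fatty acid, aromatic and nicotine catabolism, 8 higher and 6 lower of 64) to 0.880. Without the 2 blocks 10 lists passed in place of 5, among them fatty acid catabolism (adjusted p = 0.00138), TonB-dependent receptors (12 higher and 1 lower outside the blocks, 0.00982) and mobile elements (8 higher and 1 lower, 0.00201). Over all features these had adjusted p = 0.728, 0.728 and 0.777 with an estimated correlation. Osmoprotection had 3 of 18 higher, kdpA, kdpB and kdpC (0.62, 0.54 and 0.59), and 3 lower (camera adjusted p = 0.816). fry gave 9 lists an adjusted p under 0.05. Limma called 868 features, 278 higher and 590 lower, 208 of the lower ones in the blocks. The higher count became 170 and 173 without dsnc251_comp replicates 2 and 3. Scaling by library size alone gave 133 higher and 855 lower (13.5% higher, against 32%) and shifted the median of all features to −0.14.

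The last question was which genes changed in the deletion strain and changed back with the plasmid. Receptor gene BJP26_RS06795 went from 152 ± 1.52 FPKM in WT to 70.3 ± 6.93 in the deletion strain and 216 ± 22.3 in the complemented strain (SD, n = 3; log2 fold changes −1.11 and 1.6, SE 0.11 each, limma adjusted p = 3.99e-05 and 3.11e-05). The siderophore receptor gene BJP26_RS07030 went from 81.2 ± 7.06 to 39.6 ± 3.12 and back to 80.2 ± 8.19 (−1.02 and 1.00). The (2Fe-2S)-binding protein gene BJP26_RS20835 went from 413 ± 22.7 to 108 ± 14.6 and to 212 ± 39.0 (−1.94 and 0.96). The hypothetical protein genes BJP26_RS05055, BJP26_RS20450 and BJP26_RS06540 fell by 1.01, 1.51 and 1.34 and rose by 1.09, 1.00 and 0.83 on the log2 scale. Among genes going the other way, betA was at 93.0 ± 4.34, 140.1 ± 12.8 and 99.3 ± 1.81, and methionine synthase BJP26_RS13350 at 1354 ± 192, 2283 ± 356 and 1311 ± 110.2.

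In all, 42 features were called in opposite directions, 25 lower then higher and 17 higher then lower, and 2 were called lower in both. Of the 25, 6 encode TonB-dependent receptors. Against WT, 6 of the 25 were still called, 4 lower and 2 higher, and 1 of the 17 was. Of the 4, BJP26_RS20450 lost that call with limma-voom (adjusted p = 0.0894), with the length trend removed (0.235) and without WT replicates 1, 2 and 3, dsnc251 replicate 1 or any dsnc251_comp library (0.0535 to 0.146). BJP26_RS06540 lost it without WT replicates 2 and 3 or dsnc251_comp replicates 1 and 2 (0.0563 to 0.0923). Independent lists of these sizes would share 9.14 features lower then higher and 9.42 higher then lower, and simulated unchanged groups shared 0, which follows from their having no changed genes and decides nothing. The correlation of log2 fold changes across genes, which are not independent replicates, was −0.122 against −0.502 in simulated unchanged groups, with a covariance of −0.0451 against −0.0235 (difference −0.0215). The simulated correlation follows from the shared group and equal group sizes. It therefore does not show how much reversal to expect where genes do change. Without the blocks, whose genes had almost no reads in the deletion and complemented strains, the correlation was −0.307 against −0.501 and the covariance −0.0427 against −0.0236, and independent lists would share 5.46 and 9.93 features. Both comparisons contain the 3 dsnc251 libraries, too few to split, so part of the excess may come from those shared libraries. The count of 42 moved with each library left out: 135, 24 and 25 without WT replicates 1, 2 and 3, 24, 26 and 12 without dsnc251 replicates 1, 2 and 3, and 27, 21 and 18 without dsnc251_comp replicates 1, 2 and 3.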

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

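Alternatives chosen after seeing the data were those without the 2 blocks, with annotated genes only, with a length trend removed and with other list members. Apart from left-out libraries, and with the later ones included, 11 of 14 alternatives (deletion strain against WT), 12 of 14 (complemented against deletion strain) and 12 of 14 (complemented strain against WT) left the count of calls within 1.5 times. The exceptions were stricter by construction or tested fewer features. Without the 2 blocks the deletion strain had 403 calls in place of 682. With at least a 2-fold change the counts were 271, 99 and 338, and with an adjusted p under 0.01 they were 417, 95 and 479. Lists passing camera went from 4, 2 and 5 to 0, 0 and 1 with an estimated correlation. Without the 2 blocks 2 lists passed for the deletion strain and 10 for the complemented strain against WT; the cause was not tested. Features called in opposite directions went from 42 to 4 with a 2-fold change in both. Leaving out each library gave 467 to 750, 103 to 349 and 636 to 807 calls, 3 to 6, 2 to 4 and 4 to 6 lists, and 12 to 135 features in opposite directions. Where this left 1 group with 2 libraries, limma pooled the spread over the groups. Named genes kept their call under every alternative tried on them in 23 of 29, 17 of 19 and 25 of 30 cases, and 0 reversed. Those named against WT include block genes listed at 0 outside WT, which could hardly lose a call. Fitting the replicate number as a block gave 687, 314 and 942 calls, 5, 2 and 5 lists and 53 genes in opposite directions, and under this block BJP26_RS20955, BJP26_RS11805, BJP26_RS18470 and BJP26_RS20450 (complemented strain against WT) had adjusted p = 0.0519, 0.0520, 0.0610 and 0.0634. Deviations of same-numbered libraries correlated at −0.117 to 0.261 (over 0.1 in 2 of 9 pairs), and 2 of 9 libraries correlated best with their own number, so no pairing was assumed. The DESeq2 Wald test and the edgeR fits planned for raw counts were not run, because the table holds FPKM. Limma-voom on the recovered reads gave 738, 276 and 928 calls. At 3 libraries per group and 2861521 to 3239215 reads each, simulated 1.5-fold changes were recovered in 52% to 54% of genes, so smaller changes would often be missed.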

Other observations

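The tests of the blocks, of the fallen genes' variation in WT, of the receptors, of the plasmid sequence and of feature length were chosen only after the result was seen. The tests with other splits and with thinned reads were set before their results.

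Single genes of surface appendages fell in the deletion strain, while their lists did not pass camera. Of 38 genes of pili and secretion systems 5 were lower and 1 higher (adjusted p = 0.565), and of 56 flagellum and chemotaxis genes 2 were lower and 2 higher (adjusted p = 0.601). The Flp pilin genes BJP26_RS07550 and BJP26_RS07555, small subunits of tight-adherence pili, fell from 150 ± 12.9 to 56.8 ± 7.34 FPKM and from 44.1 ± 8.45 to 19.3 ± 3.55 (SD, n = 3; log2 fold changes −1.39 and −1.15, SE 0.14 and 0.19, limma adjusted p = 4.29e-05 and 0.00253). Flagellin BJP26_RS01380 fell from 36.7 ± 3.44 to 20.3 ± 1.94 (−0.82, SE 0.16, adjusted p = 0.00631) and the motor gene motA from 106 ± 13.9 to 60.9 ± 9.48 (−0.80, SE 0.14, adjusted p = 0.00410). In the complemented strain motA was at 58.2 ± 1.94, and 8 of 56 flagellum and chemotaxis genes were called lower than in WT and 1 higher (camera adjusted p = 0.311, 0.0194 without the 2 blocks, in which none of them lie; fry adjusted p = 0.0259). The list had adjusted p = 0.728 with an estimated correlation. The list of multidrug efflux did not pass camera with the SNC251 plasmid, at 2 of 41 higher and 1 lower (adjusted p = 0.974). The adaptor and permease genes BJP26_RS13500 and BJP26_RS13495 rose from 176 ± 12.8 to 326 ± 18.5 and from 199.7 ± 15.1 to 292 ± 4.25 (0.89 and 0.55, adjusted p = 0.000512 and 0.0109). The TolC family channel gene BJP26_RS07580 rose from 105 ± 10.8 to 170 ± 9.13 (0.69, adjusted p = 0.00499). The OmpA family gene BJP26_RS00255 fell from 854 ± 3.11 to 513 ± 46.0 (−0.74, adjusted p = 0.00124). These genes were chosen after their values were seen.

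The pattern most in need of follow-up is the pair of blocks with almost no reads in the deletion background. Lower depth is argued against, since 83642 reads were expected in the 6 libraries and 9 were seen (upper 95% Poisson bound 17.1). A library swapped between WT and that background is argued against as well. All 6 libraries of that background had under 1% of the expected reads and the WT libraries had 98% to 101%. A swap between the deletion and complemented strains would not show here, since both lack these reads. The residual of 0.0108% is what DNA missing from the lineage of the deletion strain could leave. Whether silent genes could leave as little was not measured, and no DNA reads were analysed here, so neither is excluded. A loss before the plasmids entered and an effect of the deletion itself cannot be told apart, since both strains of that background share it.

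The labels do not say that the WT replicates were separate cultures, so the spread between them may be technical. Part of the genes that fell in the complemented strain may belong to a gene set that also varies between the WT libraries. Over these 191 genes, WT replicate 1 lay a median of 0.4804 above the other WT libraries on the log2 scale, outside the 0.0097 to 0.0984 of 95% of 10000 random sets, and 68 of them were at least 1.5-fold above. Another 52 were within 1.2-fold, and response regulator BJP26_RS09165 was at 451, 390 and 468 FPKM in the WT libraries, so this does not cover every fallen gene. A marked loss of depth is argued against by the library sizes implied by the FPKM scale. They were 2807413 to 2945488 in the complemented strain, within the 2685223 to 2951329 of the deletion strain. The recovered totals overlapped but were somewhat lower in the complemented strain, at 3151323 to 3192104 reads against 3179155 to 3239215. Thinning all libraries to the smallest size on the FPKM scale left 183 lower calls, but with sizes so alike little change could follow. Whether the plasmid, culture state or library handling lowered these genes stays open, with 3 libraries per group and no second set of cultures.

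BJP26_RS12935 rose 9.02-fold in the complemented strain. Of the 10 nearest annotated genes, 0 were called higher. Among them BJP26_RS12905, BJP26_RS12910, BJP26_RS12915, glgX, treZ and BJP26_RS20905 were called lower (log2 fold changes −1.24 to −0.68). Plasmid sequence from this position could give the reads of BJP26_RS12935, though its surroundings were not unchanged. A predicted feature on the other strand between 2736652 and 2737040, beside it and inside glgX (BJP26_RS12940), did rise, from 35.4 ± 3.77 to 78.0 ± 11 FPKM (log2 fold change 1.11, limma adjusted p = 0.00617), while glgX and treZ fell by 0.68 and 0.94 on that scale; how reads were split between it and glgX is uncertain without a stated strand setting. A regulated gene would look alike, and the plasmid sequence is not given in the sources used here, so the explanations cannot be told apart. No feature is named snc251, and nothing here ties this position to it.

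A hypothesis for the receptors is that they follow snc251 more often than other genes. Of the 25 features lower without it and higher with the plasmid, 6 encode TonB-dependent receptors, against 76 of 4095 tested (odds ratio 18, Fisher's exact test, p = 4.48e-06). This p restates the count that prompted it, and cannot decide the hypothesis. Both calls share the 3 dsnc251 libraries, and genes under 1 control are not independent. The 42 features in opposite directions became 12 to 135 with single libraries left out. The 25 also include a predicted feature (1399610 to 1399737) inside receptor gene BJP26_RS06795, and how reads were split between them is uncertain. Further cultures with and without snc251 would be needed.

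Features called lower than in WT outside the blocks had median lengths of 478.5 bp (deletion strain) and 524.5 bp (complemented strain), against 762 bp for all tested. Of the 3885 features tested there, 613 were over 1500 bp. Among these, 24 and 32 were called lower and 70 and 86 higher. With the length trend removed, lower calls outside the blocks went from 272 to 257 in the deletion strain (225 shared). They went from 382 to 361 in the complemented strain (334 shared), which argues against length as the whole cause of the lower calls. Higher calls there went from 202 to 184 (147 shared) and from 278 to 277 (232 shared), so a smaller share of them was kept. Among features of 200 bp or less outside the blocks the lower calls went from 49 to 27 and from 60 to 33. The correction builds in that drop for them.

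Of the 10 splits of the 6 libraries in each comparison, 1, the real one, gave as many calls. That is 682, 269 and 868 against a highest of 0 in the others. The other splits mix the strains, which adds the strain differences to the spread, so low counts there are largely built in. The 10 splits are also too few for a share under 0.05, so this decides nothing.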
